A study of Mus musculus with 6 samples.

How the data were processed

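The series compared G1E-ER-GATA-1 cells transfected with non-targeting siRNA (3 arrays) and with SetD8 siRNA (3 arrays), all treated with β-estradiol for 24 h. Groups and replicate numbers were taken from the sample titles. The deposited scanner files hold spot intensity on a linear scale from 1-colour Cy3 Agilent arrays, made with Agilent Feature Extraction 10.7.3.1 per the file headers, with spatial and multiplicative detrending and surrogate values for signals near background. Probe coordinates are on mm9 per the file headers. The authors' series matrix also holds linear intensity: 100% of its values matched the processed signal of the same array within 0.006, so it is not normalized between arrays. Its column medians were 28.8, 7.15 and 76.1 for controls 1, 2 and 3 and 45.3, 23.9 and 30.1 for SetD8 1, 2 and 3. The tool limma is named in the submitters' processing notes, with no version; how the authors normalized between arrays and tested is not given in the sources used here.

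Each array had 62976 spots, 59305 of them not controls. Control spots and the 139 to 176 spots per array marked as non-uniform or population outliers were left out, and replicate spots of a probe were averaged, which left 55681 probes. The median CV of replicated probes was 10.7% to 12.8%. Probes were named through a reference gene table of assembly GRCm38.p6, used for names alone: 26762 probes matched by accession, 3819 by symbol and 639 by synonym, giving 22221 genes. The other 24461 probes were left without a reference gene, 16194 of them named in the files as genomic regions. A probe was kept if well above background on all arrays of at least 1 group, and a gene was represented by its kept probe with the highest mean, which left 14422 genes.

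In the setting fixed for the comparison, log2 of the processed signal deposited by the authors was taken minus each array's 75th percentile. Differences, SetD8 siRNA minus control siRNA, were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every Setd8 probe was also tested alone, with an exact permutation test. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

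The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Because the 75th percentile scaling called 0 genes, genes and lists are described after 1 of the alternatives fixed in advance, normexp background correction (offset 50) of the mean signal with the median local background, followed by quantile normalization between arrays. That alternative was chosen for this use after the counts under all settings had been seen. The offset makes fold changes of dim genes smaller than they are. The other alternatives fixed in advance were normexp with the 75th percentile, quantile normalization, median scaling, other filters, other gene summaries, trend and robust moderation, array weights, the replicate number or the slide as a block, the series matrix, a 1.5-fold threshold and leaving out each array. Alternatives added after seeing the data were both scalings on detected probes, control 1 as the only control, each planned choice on top of normexp and quantile normalization, and an offset of 16.

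The rule for named genes took Setd8, then, among genes past the threshold whose groups' arrays did not overlap and whose name matched the reference table, the 12 largest increases and 12 largest decreases, then up to 4 members of each list with the smallest p, and 13 fixed names. At the 75th percentile scaling it named 0 genes by size. Applied after normexp and quantile normalization, it had 205 higher and 29 lower genes to choose from and named 141 genes in all, those of the lists included. Other list members and probes without a gene that the text names were chosen after their values were seen.

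The 29 gene lists came from textbook knowledge: GATA-1-activated and GATA-1-repressed genes, globins, heme and iron, red cell membrane, lysine methyltransferases, p53 targets, DNA replication, G2/M, DNA damage, apoptosis, interferon response, unfolded protein and integrated stress response, heat shock, cholesterol, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, MYC targets and ribosome biogenesis, autophagy, RNA exosome, erythroid transcription factors, histones, imprinted and growth-arrest genes, and markers of megakaryocytes, mast cells, granulocytes and macrophages, lymphoid cells, and stromal and endothelial cells. Lists were tested with camera (preset correlation 0.01, at least 5 measured members), with an estimated correlation, on ranks, and with fry, adjusted over the lists. Some genes stand in more than 1 list, such as Bax and Bbc3 among p53 targets and apoptosis genes. Each list's median was set against 10000 random lists matched on mean expression in 20 bins.

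The limma test was run on simulated data with 14422 genes, 200 of them changed, and independent noise for each gene. Values were drawn around each setting's normalized means with its own spread, so the normalization itself was not run on simulated data. With the spread of the 75th percentile scaling, 0% of 2-fold and 0% of 4-fold changes were recovered with 0 false calls. With that of normexp and quantile normalization, 62% and 94% were recovered, with 13 false calls and 0 of wrong sign. These shares reflect the spread of each setting and cannot show whether either normalization keeps true changes. No array was left out of the comparison.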

Results

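RNA was profiled in G1E-ER-GATA-1 cells, a mouse erythroid progenitor line that lacks its own Gata1 and carries GATA-1 fused to the ligand-binding domain of the estrogen receptor, so that β-estradiol starts red cell maturation. Cells received non-targeting siRNA or siRNA against Setd8 (SetD8, current symbol Kmt5a), the enzyme that monomethylates lysine 20 of histone H4. Transfections were done at 0 h and 24 h, β-estradiol was given for 24 h, and RNA was taken at 48 h. The series held 3 control siRNA arrays and 3 SetD8 siRNA arrays, each hybridised with Cy3-labelled cRNA in 1 colour. The comparison asks which transcripts differ when Setd8 is depleted during GATA-1-driven maturation. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

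The control arrays differed from each other more than the SetD8 arrays did. The share of the 59305 non-control spots well above background was 64.1% on control 1, 40.2% on control 2 and 82.5% on control 3, against 68.6%, 60.3% and 64.8% on SetD8 1, 2 and 3. The 75th percentile of the processed signal lay between 132 and 258 intensity units, and no spot was saturated (0 on each array). The lowest correlation between 2 arrays across genes at the 75th percentile scaling was 0.869, between control 2 and control 3, whereas the SetD8 arrays correlated at 0.980 to 0.986. Control 1, SetD8 1 and SetD8 2 shared slide 1, control 3 and SetD8 3 shared slide 3, and control 2 was alone on slide 2, scanned on another day. A fit with slide as a block therefore takes no difference from control 2, and compares the SetD8 arrays with controls 1 and 3 alone. The number of arrays limits the precision of every value.

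Setd8 was lower on every SetD8 array than on every control array, on both of its probes. On the brighter probe (chromosome 5, 124911883 to 124911942, mm9) the log2 signal relative to the array's 75th percentile was 4.34, 4.95 and 3.14 on controls 1, 2 and 3 and 2.07, 1.82 and 1.83 on SetD8 1, 2 and 3. The difference was −2.24 ± 0.51 (SE), 4.72-fold lower, with a limma p of 0.00334 unadjusted. On the dimmer probe (124897355 to 124900704) the signal was 2.05, 1.99 and 1.79 against 0.34, 0.38 and 1.00, a difference of −1.37 ± 0.35 (SE), 2.58-fold lower. The exact two-sided permutation p was 0.1 for each probe, the smallest that 3 against 3 arrays allow. Over all 14422 genes the adjusted p for Setd8 at this scaling was 0.683. After normexp background correction and quantile normalization the difference was −2.07 ± 0.15 (SE), 4.2-fold lower, with an adjusted p of 0.00848. It was then −2.07 within slide 1 and −1.99 within slide 3, and −2.04 with an adjusted p of 0.0409 with slide as a block.

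**Figure D1:**
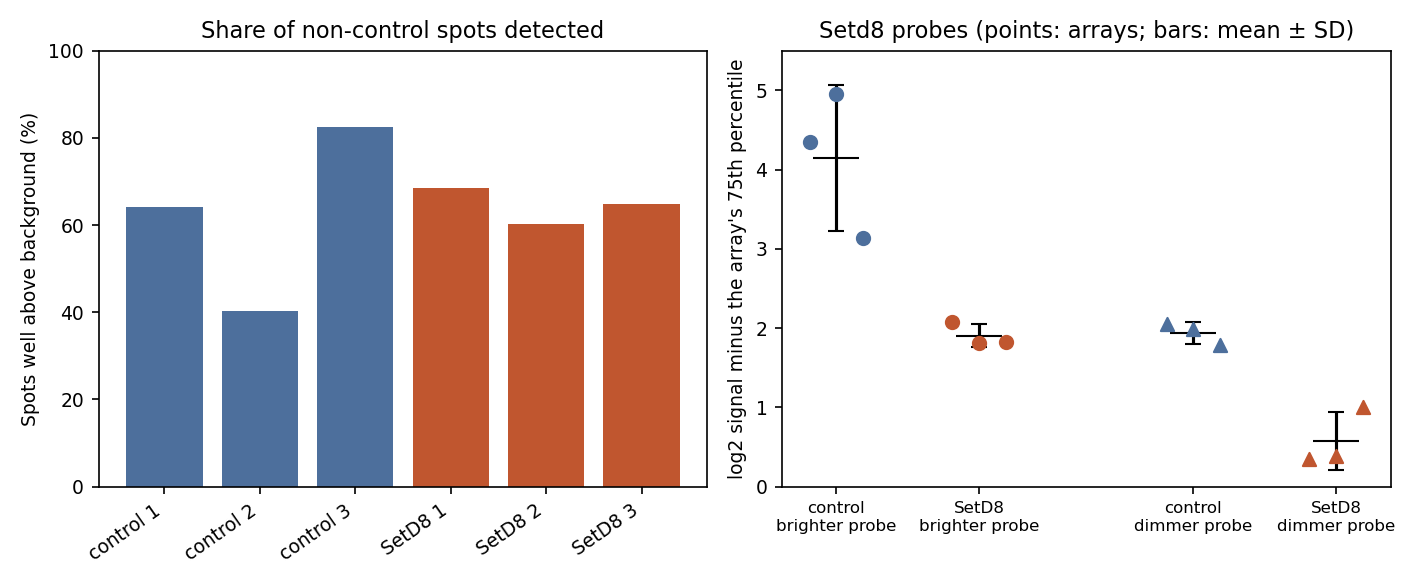
Left, share of non-control spots well above background on each array, in percent, from 40.2% on control 2 to 82.5% on control 3. Right, log2 signal of both Setd8 probes minus the array's 75th percentile, with a point for each array and bars for mean ± SD (n = 3); all SetD8 arrays lie below all control arrays on each probe.

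After SetD8 siRNA, transcripts of p53 target genes and of the interferon response were higher as groups. Those of core and linker histones, DNA replication, mitosis, MYC targets with ribosome biogenesis, and glycolysis with hypoxia were lower as groups. Both statements rest on camera with its preset correlation after normexp and quantile normalization. With an estimated correlation 0 of these lists passed, with adjusted p of 0.0893 to 0.301. The embryonic globin gene Hbb-bh1 was 5.74-fold higher after normexp and quantile normalization, while most genes of the GATA-1 programme did not pass the test. The strength of these statements depends on the scaling. At the 75th percentile scaling limma called 0 genes higher and 0 lower at an adjusted p under 0.05, with 444 genes at an unadjusted p under 0.05. That is a smaller share than the 0.05 that chance alone gives on average. After normexp and quantile normalization, limma called 211 genes higher and 34 lower of 14422, with 2275 at an unadjusted p under 0.05, a larger share. The median residual SD was 0.52 (log2) in the first setting and 0.21 in the second. The groups' arrays did not overlap for 7.57% of genes in the first and 23.7% in the second, where chance gives 10%.

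The values for genes and lists given next are those after normexp and quantile normalization, with adjusted p-values from limma over all 14422 genes, unless another setting is named. With slide as a block 13 genes were called higher and 1 lower, all 14 among the 245. Besides Setd8, Dglucy, Kank3, Phlda3, Dcxr, Hbb-bh1, Rec8, Aqp8, Nme4 and Bst2 were among these 14, and every other gene named here as changed lost its call with slide as a block. All 245 kept their sign there, with 2 residual degrees of freedom against 4 without the block. Without control 1, SetD8 1 or SetD8 2, limma called 0 genes, with 1504, 1814 and 1721 at an unadjusted p under 0.05. Each is a larger share than the 0.05 that chance gives on average. Without SetD8 3, 5 genes were called, without control 2, 99, and without control 3, 207. All 245 genes kept their sign in each of these fits. At least 205 higher and 29 lower of them had groups whose arrays did not overlap, which fixes the sign on a given probe. Kept signs, here and with slide as a block, are therefore no check on those genes. The split was 36 higher and 1 lower with normexp and the 75th percentile, and 439 higher and 158 lower when normexp and quantile normalization was kept but only the 10818 genes with a probe well above background on all arrays were tested. Median scaling moved the median difference of all genes to −0.45 (log2) and the 75th percentile over detected probes moved it to 0.17, against 0.04 at the 75th percentile scaling and 0.03 after normexp and quantile normalization.

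The 12 largest increases included 3 members of the p53 list and 1 globin. Dglucy, D-glutamate cyclase (probe at chromosome 12, 102110492 to 102110551, mm9), rose 10.9-fold, from a log2 signal of 7.59 ± 0.18 to 11.03 ± 0.40 (SD, n = 3 arrays each), with an adjusted p of 0.00599 by limma. Pde6a, a phosphodiesterase subunit of rod photoreceptors (chromosome 18, 61449307 to 61449366), rose 10.4-fold (adjusted p = 0.0101). Ak1, adenylate kinase 1 (chromosome 2, 32490509 to 32490568), rose 9.07-fold (adjusted p = 0.0101), and Kank3 rose 8.24-fold (adjusted p = 0.00848). Phlda3 rose 6.56-fold, Dcxr 6.10-fold, Rec8, a meiotic cohesin subunit, 5.70-fold, Trp53inp1 5.06-fold, Scamp5 5.02-fold, the water channel Aqp8 4.67-fold and Nme4, a mitochondrial nucleoside diphosphate kinase, 4.28-fold. The probes of a gene could differ in size: the log2 difference was 1.91 to 3.44 for Dglucy, 2.17 to 3.04 for Kank3 and 1.23 to 2.22 for Aqp8. With slide as a block Pde6a (adjusted p = 0.0505), Ak1 (0.0533), Trp53inp1 (0.0574) and Scamp5 (0.0657) were no longer past the threshold. Their log2 differences were then 3.45, 3.37, 2.33 and 2.51, against 3.38, 3.18, 2.34 and 2.33 without the block. With slide as a block at the 75th percentile scaling, where limma took 1 spread for all genes, all 12 were past it, with adjusted p from 2.5e-14 for Dglucy to 5.7e-04 for Nme4. With 1 spread the p follows the size of the difference, and the 12 were picked for large differences on these same arrays. Passing there is therefore no separate support for them.

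The largest decreases after Setd8 itself were smaller than the increases. Trib3, a pseudokinase induced by the stress-responsive factor ATF4 (chromosome 2, 152163161 to 152163220), fell by 1.22 on the log2 scale (2.33-fold, SE 0.14, adjusted p = 0.0193). Hk2, hexokinase 2, was 2.22-fold lower (adjusted p = 0.0468) and the linker histone gene H1f5 2.08-fold lower (adjusted p = 0.0242). Sdad1 was 2.06-fold, Dnajc21 2.01-fold and the small nucleolar RNA host gene Snhg15 2.00-fold lower, and the splicing factor Srsf7 (1.93-fold), malic enzyme Me1 (1.89-fold), Hnrnpa0 (1.85-fold), the cationic amino acid transporter Slc7a1 (1.84-fold) and the folate enzyme Mthfd1l (1.79-fold) completed the 12. Apart from Setd8, none of these decreases was past the threshold with slide as a block, where adjusted p ran from 0.0582 for Trib3 to 0.12 for Srsf7, nor with slide as a block at the 75th percentile scaling. After normexp and quantile normalization the block gave log2 differences of −1.25 for Trib3 and −0.89 for Srsf7, against −1.22 and −0.95 without it. The decreases of Dnajc21 ranged from −1.0 to −0.28 over its probes.

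**Figure D2:**
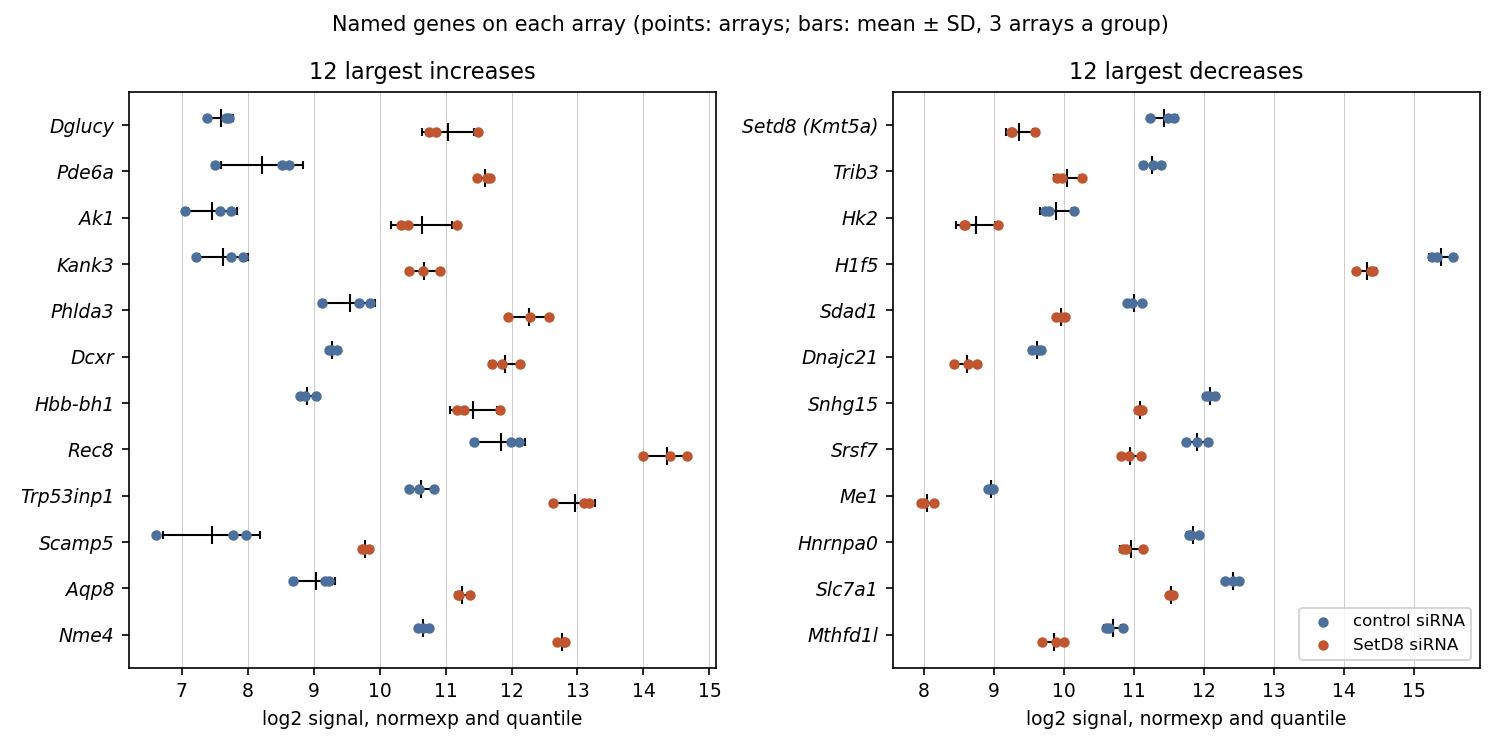
Log2 signal after normexp and quantile normalization of the 12 genes with the largest increases (left) and the 12 with the largest decreases (right), with a point for each array and bars for mean ± SD (n = 3 arrays a group). Dglucy rose from 7.59 to 11.03 and Setd8 fell from 11.43 to 9.36. No control array overlaps a SetD8 array for any of the genes drawn, because the rule that chose them required it.

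Genes activated by p53 were higher as a group. Of the 28 measured members of this list 11 rose, 0 fell and 17 did not pass; adjusted over the list alone, 16 were higher and 0 lower. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 2.63-fold (log2 1.39 ± 0.14 SE, adjusted p = 0.0126), although its 3 probes ranged from −0.02 to 1.72. The pro-apoptotic genes Bbc3 (2.26-fold, adjusted p = 0.0193) and Bax (2.18-fold, adjusted p = 0.0218) and Ccng1 (2.97-fold, adjusted p = 0.0154) rose as well, whereas Mdm2, the p53 ubiquitin ligase, had a log2 difference of 0.63 with an adjusted p of 0.0509. With slide as a block 2 of the 11 kept their call, Dcxr and Phlda3, and adjusted p was 0.0574 for Cdkn1a, 0.058 for Ccng1, 0.071 for Bbc3 and 0.0773 for Bax. The median log2 difference of the list was 0.86 (camera adjusted p = 2.9e-12; adjusted p = 0.20 with an estimated correlation), and 0.91 at the 75th percentile scaling. It was 0.69 within slide 1, 0.99 within slide 3 and 0.95 with slide as a block (camera adjusted p = 3.8e-13).

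**Figure D3:**
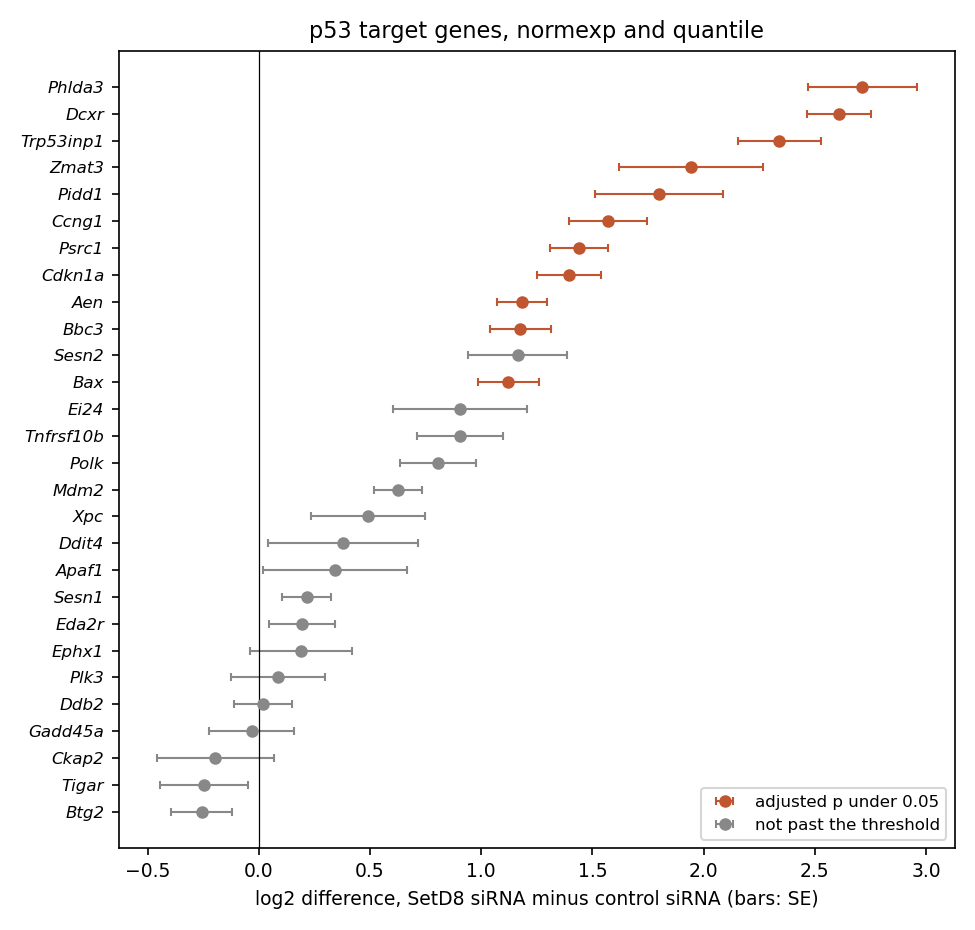
Log2 difference, SetD8 siRNA minus control siRNA, of the 28 measured p53 target genes after normexp and quantile normalization, with bars for the SE. The 11 coloured genes passed the adjusted threshold and range from Bax at 1.12 to Phlda3 at 2.71.

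The interferon response genes, which cells switch on upon interferon or viral RNA, were also higher as a group. The labels tell 1 SetD8 siRNA reagent apart, so an effect of the reagent cannot be told from the loss of Setd8 here. Of 25 measured members 2 rose, 0 fell and 23 did not pass, and 24 had a positive difference; adjusted over the list alone, 6 were higher and 0 lower. Bst2, tetherin, rose 3.31-fold (adjusted p = 0.0101) and the immunoproteasome subunit Psmb9 rose by 0.81 on the log2 scale (adjusted p = 0.03), while Oas3 (0.60, adjusted p = 0.0527) and Ddx58 (0.70, adjusted p = 0.062) did not pass. With slide as a block adjusted p was 0.0409 for Bst2 and 0.1 for Psmb9. The list's median was 0.46 (camera adjusted p = 4.0e-08; adjusted p = 0.0893 with an estimated correlation), 0.37 within slide 1, 0.64 within slide 3 and 0.48 with slide as a block (camera adjusted p = 1.7e-08).

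Genes of the dividing cell were lower as groups, mostly with small differences for single genes. Among 43 DNA replication and G1/S genes, 1 rose (Rfc2, a replication factor C subunit, log2 0.74, adjusted p = 0.0387, 0.136 with slide as a block), 0 fell and 42 did not pass, but 40 had a negative difference; adjusted over the list alone, 1 was higher and 19 were lower. Values for Pcna, the replication clamp, were −0.73 ± 0.15 (SE, adjusted p = 0.0724) and for Mcm10 −0.68 (adjusted p = 0.0604). The list's median was −0.36 (camera adjusted p = 8.7e-14; adjusted p = 0.20 with an estimated correlation), with −0.43 within slide 1, −0.29 within slide 3 and −0.33 with slide as a block (camera adjusted p = 5.8e-10). Of 40 genes of G2/M and mitosis 0 passed in either direction and 36 had a negative difference; adjusted over the list alone, 0 were higher and 19 lower, with Kif11, a spindle kinesin, at −0.67 (adjusted p = 0.0669) and Top2a at −0.52 (adjusted p = 0.108). Their median was −0.35 (camera adjusted p = 7.4e-13; adjusted p = 0.10 with an estimated correlation), with −0.41 within slide 1, −0.29 within slide 3 and −0.33 with slide as a block (camera adjusted p = 8.2e-10).

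Core and linker histone genes had the lowest median of the 29 lists in this setting. Of 35 measured members 0 rose, 1 fell (H1f5) and 34 did not pass; adjusted over the list alone, 0 were higher and 18 lower. H3c1 had a log2 difference of −0.76 (adjusted p = 0.0593) and H2ax, whose product marks DNA breaks, −0.87 (adjusted p = 0.0744). The median was −0.52 (camera adjusted p = 7.9e-14; adjusted p = 0.20 with an estimated correlation), −0.60 within slide 1, −0.61 within slide 3 and −0.61 with slide as a block (camera adjusted p = 5.5e-12). Many histone genes are near-identical copies, as are the adult globin genes, so their probes may share signal and are uncertain as single genes. Among 34 DNA damage and repair genes 0 passed in either direction (adjusted over the list alone, 0 higher and 2 lower, Fancb and H2ax). Their median was −0.21 (camera adjusted p = 1.1e-05; adjusted p = 0.30 with an estimated correlation), −0.24 within slide 1, −0.05 within slide 3 and −0.17 with slide as a block (camera adjusted p = 7.7e-04), while slide as a block ended the call at the 75th percentile scaling (−0.13, camera adjusted p = 0.14).

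The list of MYC targets and ribosome biogenesis and that of glycolysis and hypoxia were lower as groups, and the parts of each list were not tested apart. Of 36 MYC target and ribosome biogenesis genes 1 fell (Mrto4, log2 −0.84, adjusted p = 0.0242, 0.114 with slide as a block), 0 rose and 34 had a negative difference; adjusted over the list alone, 0 were higher and 11 lower. Nop58, a nucleolar protein of small nucleolar ribonucleoproteins, stood at −0.70 (adjusted p = 0.0636). The list's median was −0.35 (camera adjusted p = 3.5e-11; adjusted p = 0.30 with an estimated correlation), −0.28 within slide 1, −0.37 within slide 3 and −0.32 with slide as a block (camera adjusted p = 1.0e-09). Of 29 glycolysis and hypoxia genes 1 fell (Hk2), 0 rose and 28 did not pass; adjusted over the list alone, 14 were lower and 1 higher, the muscle phosphofructokinase Pfkm. The glucose transporter gene Slc2a1 had a difference of −1.28 ± 0.23 (SE, adjusted p = 0.0572) and Vegfa −1.22 (adjusted p = 0.0906). The median was −0.47 (camera adjusted p = 1.5e-08; adjusted p = 0.20 with an estimated correlation), −0.58 within slide 1, −0.39 within slide 3 and −0.50 with slide as a block (camera adjusted p = 1.0e-09).

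Few single genes of the erythroid programme passed after normexp and quantile normalization, and the GATA-1-activated and globin lists did not pass camera's test there. Of 37 GATA-1-activated genes 1 rose, Tspo2, a translocator protein of red cell precursors (log2 0.99, adjusted p = 0.0242, 0.0929 with slide as a block), 0 fell and 36 did not pass; adjusted over the list alone, 1 was higher and 1 lower, Ank1. The list's median was 0.07 (camera adjusted p = 0.533) and −0.11 at the 75th percentile scaling (camera adjusted p = 0.199), so its sign changed with the scaling. By fry's test for change in either direction, which does not compare a list with other genes, adjusted p was 3.2e-05 for GATA-1-activated genes, 8.5e-05 for heme genes, 9.7e-05 for globins and 7.9e-05 for erythroid transcription factors, against 0.602, 0.606, 0.00279 and 0.606 at the 75th percentile scaling. After normexp and quantile normalization every list passed this fry test except ribosomal proteins (0.0666) and mast cell (0.485), lymphoid (0.485) and stromal markers (0.464). Passing it therefore does not set the erythroid lists apart. Among 8 globin genes 1 rose, Hbb-bh1, from a log2 signal of 8.90 ± 0.12 to 11.42 ± 0.35 (SD, n = 3 arrays each; probe at chromosome 7, 110990209 to 110990268), with an adjusted p of 0.00881 by limma, 0 fell and 7 did not pass; adjusted over the list alone, 2 were higher and 2 lower. The embryonic gene Hbb-y had a difference of 0.95 (adjusted p = 0.126), and the probe that the array design names Hbb-b1, now Hbb-bt, 1.20 ± 0.49 (SE, adjusted p = 0.303). Hba-a1 was the brightest gene on the arrays, so that quantile normalization set it equal and gives no information on it. The globin list's median was 0.24 (camera adjusted p = 0.457), and the list passed in 4 of the 23 alternative settings, among them slide as a block at the 75th percentile scaling (median 0.37, camera adjusted p = 0.00165), where Hbb-y had 1.76 (adjusted p = 0.0234). Slc4a1, the red cell anion exchanger, had a difference of −1.19 ± 0.38 (SE, adjusted p = 0.194), and Alas2, the erythroid heme synthesis enzyme, 0.03 (adjusted p = 0.954). Gata1 had −0.08 (adjusted p = 0.819), but the line lacks its own Gata1, so this value says nothing on the native gene.

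Genes that GATA-1 represses during maturation were slightly higher as a group. Of 21 measured members 2 rose, the intermediate filament gene Vim (log2 1.10, adjusted p = 0.011, 0.0651 with slide as a block) and Samsn1 (0.96, adjusted p = 0.0471, 0.124 with slide as a block, with a difference of 0.11 on its weaker probe), 0 fell and 19 did not pass; adjusted over the list alone, 3 were higher and 0 lower. Gata2 and Kit, classical targets of this repression, had differences of −0.00 (adjusted p = 0.999) and 0.19 (adjusted p = 0.798), and Myc −0.41 (adjusted p = 0.562). The median was 0.27 (camera adjusted p = 0.004; adjusted p = 0.30 with an estimated correlation), 0.24 within slide 1, 0.35 within slide 3 and 0.25 with slide as a block (camera adjusted p = 3.7e-04), and it was positive under 21 of the 23 alternative settings and negative under 2, median scaling (−0.39) and the arrays without control 3 (−0.24). Megakaryocyte markers were higher for 2 of 15 members, Itgb3 (0.80, adjusted p = 0.0468, 0.125 with slide as a block) and Gp1ba (0.79, adjusted p = 0.0471, 0.114 with slide as a block), and 13 did not pass; adjusted over the list alone, 3 were higher and 0 lower. Their median of 0.34 did not pass as a list (camera adjusted p = 0.0707), while that of 0.42 at the 75th percentile scaling did (camera adjusted p = 0.00941; adjusted p = 0.589 with an estimated correlation), a call that slide as a block ended (camera adjusted p = 0.422).

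Lysine methyltransferases other than Setd8 showed few changed genes. Among 16 genes of H4K20 and related lysine methylation, Setd8 fell, Ehmt2, a histone H3 methyltransferase, rose (log2 0.91, adjusted p = 0.0346, 0.128 with slide as a block) and 14 did not pass, with the same 1 higher and 1 lower adjusted over the list alone. Kmt5b and Kmt5c, which add further methyl groups to the mark that Setd8 places, had differences of −0.48 ± 0.19 (SE, adjusted p = 0.306) and −0.04 (adjusted p = 0.904). The list's median was −0.12 (camera adjusted p = 0.0629) and −0.31 at the 75th percentile scaling (camera adjusted p = 0.004; adjusted p = 0.773 with an estimated correlation), Setd8 included, where slide as a block ended the call (−0.05, camera adjusted p = 0.371).

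With camera's preset correlation 12 of the 29 lists passed in this setting and 21 at the 75th percentile scaling. With an estimated correlation 0 passed in either, and fry, which asks whether a list's genes move one way without comparing them with other genes, gave 10 and 1. The p53, interferon, histone and glycolysis lists passed in all 23 alternative settings of scaling, filter, gene summary, model and left-out array, and kept their sign in all of them. The replication, G2/M and MYC lists kept their sign in all 23 and passed in 22, the exception being the arrays without control 2, with medians of −0.27, −0.25 and −0.24. Among the 23, the 1.5-fold threshold does not enter the list test, so it could not change a list. The series matrix, and the setting with flagged spots kept, used nearly the same values as the 75th percentile scaling. The 23 are therefore not separate checks. Medians within slide 3 at the 75th percentile scaling, where control 3 had the raised share of detected spots, were 0.20 for replication, 0.26 for G2/M, 0.18 for MYC targets and 0.01 for glycolysis genes, above 0, while those within slide 1 were −0.71, −0.73, −0.56 and −0.90. Other lists described as lower were above 0 within slide 3 as well, with 0.45 for DNA damage, 0.41 for RNA exosome and 0.35 for stress response genes. The p53 list had 1.46 and the histone list −0.09 within slide 3 at that scaling.

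**Figure D4:**
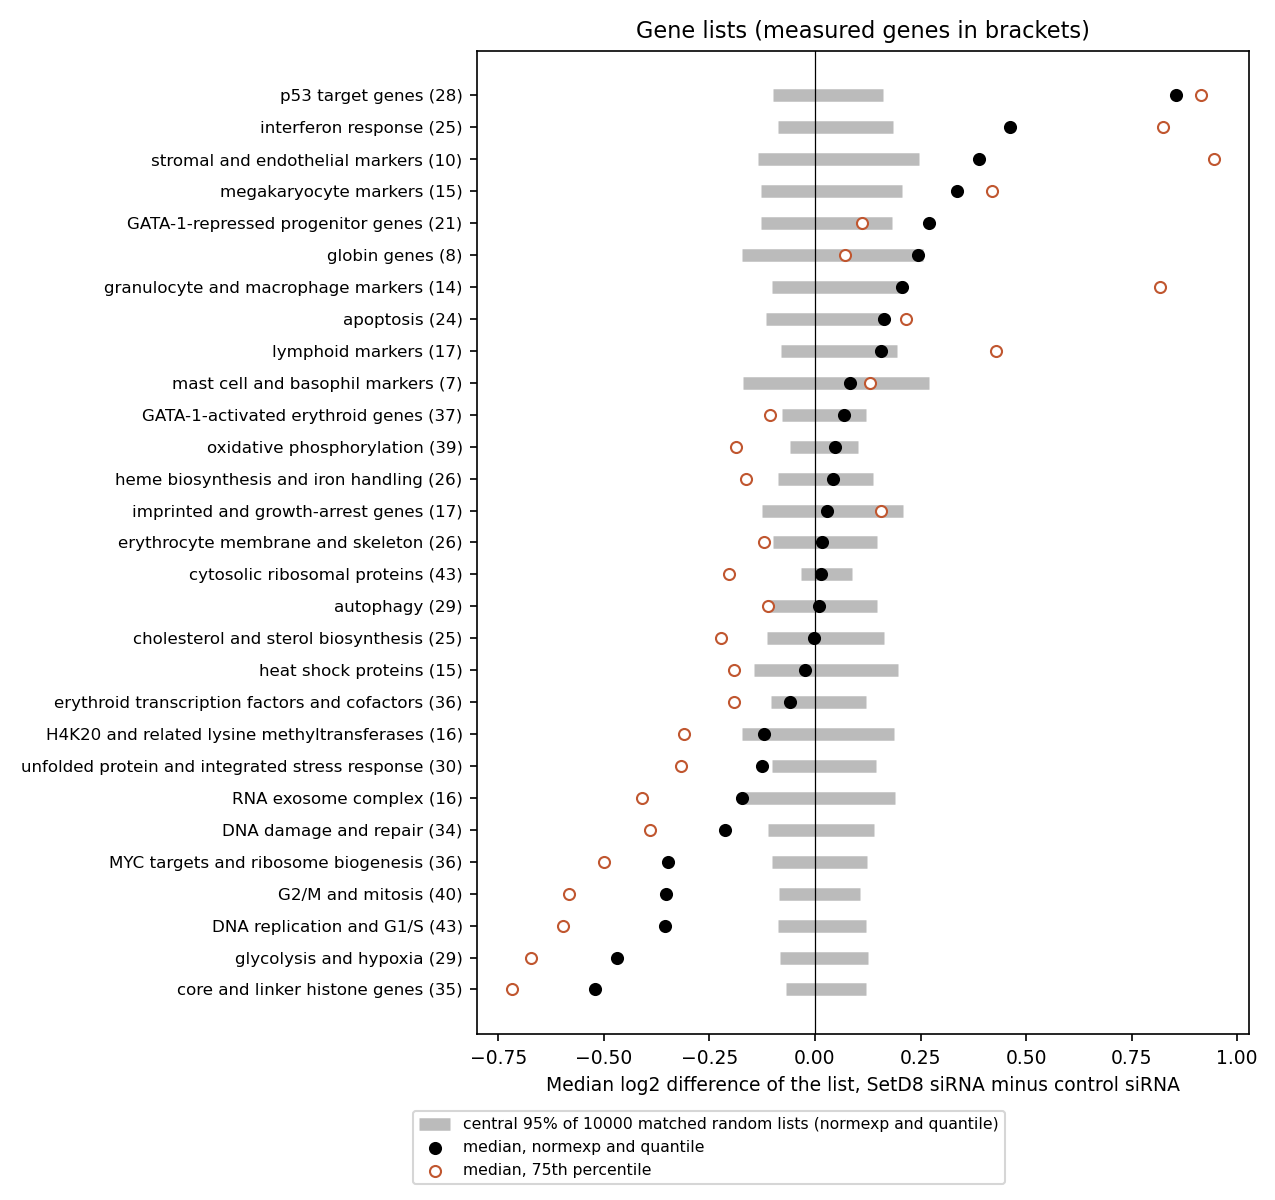
Median log2 difference, SetD8 siRNA minus control siRNA, of the 29 gene lists with the number of measured genes in brackets, after normexp and quantile normalization (filled points) and at the 75th percentile scaling (open points), with grey bars for the central 95% of 10000 random lists matched on expression. The p53 list lies at 0.86 and the histone list at −0.52, both outside the grey bars, while the ribosomal protein list lies at 0.01 in 1 setting and −0.20 in the other.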

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

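Of the tests on the control arrays, those of the slide, of the scan day and of exchanged arrays were chosen only after the result was seen, as were the test of a difference between slides for the p53 targets and that of every probe after normexp and quantile normalization. Among the 30968 kept probes, 11765 had no reference gene and stood outside the comparison of genes; of these, 8 were higher and 0 lower after SetD8 siRNA (limma, adjusted over all kept probes, normexp and quantile normalization). This signal in unused probes, above the level on the control arrays, is what marked each of them for a second look. The control and SetD8 arrays did not overlap on any of the 8. The probe at chromosome 9, 96677851 to 96677910 (mm9), had a log2 difference of 1.59 (3.01-fold, adjusted p = 0.018). The probe of 1700016F12Rik at chromosome 5, 97281886 to 97281945, had 1.57 (adjusted p = 0.0256) and a transcript probe at chromosome 18, 62343990 to 62344049, 1.52 (adjusted p = 0.0301). In 1 region of chromosome 5, 3 probes were higher: 1.23 at 122048399 to 122048458 (adjusted p = 0.0242), 1.14 at 122048494 to 122048553 (adjusted p = 0.032) and 1.08 at 122048339 to 122048398 (adjusted p = 0.042). The other 2 lay at chromosome 15, 78384772 to 78384831, with 1.15 (adjusted p = 0.0208), and at chromosome 11, 120086860 to 120086919, with 0.97 (adjusted p = 0.0463).

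The share of spots well above background ranged from 40.2% to 82.5% among the control arrays. The slide does not account for control 3, since SetD8 3 on the same slide differed from it by −17.7 percentage points, while the SetD8 arrays lay within 8.3 points of each other. Exchanged control and SetD8 arrays were excluded by Setd8, whose brighter probe was 1.07 (log2) higher on the lowest control than on the highest SetD8 array, and which did not overlap on the other probe either. An added signal on dim region and gene probes alike may explain control 3. On the log2 processed signal before scaling, dim region probes were 1.27 and level-matched dim gene probes 1.24 higher than on control 1, a gap of 0.0254. Bright probes were at −0.25, which an added signal alone would not give. The log2 75th percentile was 8.01 on control 3 against 7.54 on control 1, so the dim shifts would be smaller at the 75th percentile scaling. Values for control 2 below are before scaling as well. Negative control spots argue against a signal added whatever a spot measures. Their mean signal was 59.1 on control 3, 52.8 on control 1 and 63.8 on control 2. The median processed signal of non-control spots was 78.6, 31.0 and 8.35 on these arrays, in the same order. For control 2 dim region probes were −1.89 and dim gene probes −1.95 from control 1, against 0.38 for bright probes, so dim probes of both kinds were lower alike; its slide and scan day cannot be told apart from the array itself, as 0 other arrays shared either, and no biological explanation was tested.

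The higher p53 targets have a biological explanation in the design, the loss of Setd8, and several technical ones. An intensity trend left by the normalization was excluded, since the list's median lay at percentile 100 of 10000 lists matched on expression, whose central 95% ran from −0.10 to 0.16. A difference between slides was excluded, since the smaller of the medians within slides was 0.69 (log2). An effect of the siRNA other than on Setd8 stays open, because the labels tell 1 SetD8 siRNA reagent apart, so the change may come from the reagent or from the loss of Setd8.

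At the 75th percentile scaling ribosomal protein genes had a median of −0.20 and stromal markers of 0.95. An intensity trend left by that scaling may explain the ribosomal protein genes, whose median lay at percentile 42.3 of matched lists. It does not account for all of the stromal markers, at percentile 98.5, but SetD8 3 stood apart there: Sparc was 4.18 on it against −3.69 to −0.61 on the others, Col1a2 1.47 against −3.34 to −0.59 and Col3a1 0.62 against −4.98 to −2.06. The stromal median was 0.48 without SetD8 3 (camera adjusted p = 0.0278), 1.77 without SetD8 1, 1.52 without SetD8 2 and 0.33 without control 2, no longer past the threshold (0.0534). No biological explanation was tested for either list.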

How the results depend on the processing

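Both scalings on detected probes, control 1 as the only control, and every alternative on top of normexp and quantile normalization were chosen only after the data were seen. Setd8 kept its sign under all 24 alternatives, from −2.74 (without control 3) to −1.80 (mean over probes) on the log2 scale, and its adjusted p ran from 2.2e-05 to 1.00. It passed the threshold with normexp and quantile normalization (−2.07), normexp with the 75th percentile (−2.24), quantile normalization (−2.10), probes well above background on all arrays (−2.24), array weights (−2.42), slide as a block (−1.93), the 75th percentile over detected probes (−2.11) and quantile normalization over detected probes (−2.10). Leaving out each array gave differences of −2.74 to −1.84 for Setd8, lowest without control 3 and highest without control 2. With probes well above background on all arrays, and with slide as a block, limma took 1 spread for all genes. The lowest adjusted p of Setd8, 2.2e-05, came from the first of these. Calls and counts in these 2 settings therefore do not weigh each gene's own spread. Genes called were 211 higher and 34 lower with normexp and quantile normalization, 36 and 1 with normexp and the 75th percentile, 43 and 2 with quantile normalization, 96 and 9 with probes well above background on all arrays, 18 and 0 with trend and robust moderation, 1397 and 1809 with array weights (10.2 for control 1 against 0.149 for control 2 and 0.124 for control 3, so in effect on 1 control array), 118 and 12 with slide as a block, 121 and 10 with the 75th percentile over detected probes, and 462 and 174 with quantile normalization over detected probes. The other alternatives, apart from the arrays without control 2, gave 0 with limma, with 31 (median scaling) to 3549 (without control 3) at an unadjusted p under 0.05. These unadjusted counts run from below to above the share of 0.05 that chance gives on average. Leaving out each array gave 0 to 74 higher and 0 to 91 lower, with 74 and 91 without control 2 and 0 without any other. The replicate block gave 0 and 0 genes (339 at an unadjusted p under 0.05, against 444), and on top of normexp and quantile normalization 0 and 0 (1953 against 2275). Deviations of same-numbered arrays correlated at 0.24, −0.27 and −0.37, and only arrays numbered 1 correlated best with their own number, so the numbers were not taken to pair the samples, although the arrays numbered 1 shared slide 1 and those numbered 3 slide 3.

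On top of normexp and quantile normalization the counts were 173 and 23 with no filter, 439 and 158 with probes well above background on all arrays, 165 and 25 with the mean over probes, 94 and 6 with every probe tested, 639 and 334 with trend and robust moderation, 1145 and 917 with array weights, 13 and 1 with slide as a block, 211 and 34 with the 1.5-fold threshold, 115 and 9 with an offset of 16, and 24 and 3 with control 1 as the only control. Leaving out each array gave 0 to 174 higher and 0 to 33 lower. Of the gene lists, 21 passed at the 75th percentile scaling, 12 with normexp and quantile normalization, 11 with quantile normalization, 11 with slide as a block, 13 with quantile normalization over detected probes, 0 with an estimated correlation and 1 with fry; leaving out each array gave 6 to 23, and after normexp and quantile normalization 11 to 15.

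Among lists past the threshold in at least 1 of the settings compared, the test pointed the other way than at the 75th percentile scaling with these medians: with normexp and quantile normalization, heme 0.0429 and oxidative phosphorylation 0.0474; with quantile normalization, heme 0.0417; with slide as a block, heme 0.10, oxidative phosphorylation 0.0851, ribosomal proteins 0.0474 and erythroid transcription factors 0.0658, while lymphoid markers had 0.16 and a test direction down; with quantile normalization over detected probes, heme 0.0186, oxidative phosphorylation 0.0300 and ribosomal proteins 0.0135. Leaving out each array gave medians from −0.578 to 0.146 for heme, −0.559 to 0.129 for oxidative phosphorylation, −0.482 to 0.0780 for ribosomal proteins, −0.581 to 0.0915 for erythroid transcription factors, −0.549 to 0.0781 for heat shock and −0.0707 to 0.855 for lymphoid markers, each turning sign without control 2 and lying furthest the other way without control 3. The slide block takes no difference from control 2 either, so it is not a check apart from leaving that array out. The cause was not tested. Medians alone changed sign more widely over the 23 alternatives: they were positive in 6 for GATA-1-activated genes and autophagy, in 5 for heme, red cell membrane, oxidative phosphorylation and ribosomal proteins, and in 2 for heat shock, cholesterol and erythroid transcription factors, and negative in 2 for GATA-1-repressed genes, apoptosis and lymphoid markers, 3 for globins, 7 for imprinted genes, 1 for megakaryocyte and 5 for mast cell markers. Values under alternatives other than a left-out array were also compared with those at the 75th percentile scaling, where 0 genes passed. For named genes, 2136 values kept their direction and stayed short of the threshold, 312 moved past it and 58 moved otherwise. These counts do not measure how stable the calls after normexp and quantile normalization are. For lists the numbers were 400 kept, 51 no longer past, 7 newly past, 24 moved and 11 reversed. Dim probes limit what scaling can settle, since 40.2% of spots on control 2 and 82.5% on control 3 were well above background.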

Other observations

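Of the tests given here, those with slide as a block after normexp and quantile normalization were chosen only after the result was seen. Values are after normexp and quantile normalization unless another setting is named, with adjusted p-values from limma. Stress response genes were lower as a group: of 30 members of the unfolded protein and integrated stress response 1 fell (Trib3), 0 rose and 29 did not pass; adjusted over the list alone, 1 was higher (Sesn2, also a p53 target) and 8 were lower. Shmt2, the mitochondrial serine hydroxymethyltransferase, had a difference of −0.66 (adjusted p = 0.0735). The median was −0.13 (camera adjusted p = 5.6e-04; adjusted p = 0.20 with an estimated correlation), −0.22 within slide 1, −0.13 within slide 3 and −0.12 with slide as a block (camera adjusted p = 0.0025); at the 75th percentile scaling slide as a block ended the call (camera adjusted p = 0.175). Of 16 RNA exosome genes 0 passed in either direction, with Dis3, a catalytic subunit, at −0.64 (adjusted p = 0.0676); adjusted over the list alone, 0 were higher and 3 lower. Their median was −0.17 (camera adjusted p = 2.9e-04; adjusted p = 0.20 with an estimated correlation), −0.13 within slide 1, −0.16 within slide 3 and −0.11 with slide as a block (camera adjusted p = 0.0038), and at the 75th percentile scaling slide as a block ended this call too (camera adjusted p = 0.335). Apoptosis genes had 2 of 24 members higher, Bbc3 and Bax, both also p53 targets, and 22 not past; adjusted over the list alone, 6 were higher and 2 lower. Their median was 0.16 (camera adjusted p = 0.038; adjusted p = 0.30 with an estimated correlation), 0.24 within slide 1, 0.17 within slide 3 and 0.17 with slide as a block (camera adjusted p = 0.034), and at the 75th percentile scaling it did not pass (adjusted p = 0.255).

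Other lists did not pass in this setting, though single members did, all of which lost their call with slide as a block (adjusted p = 0.114 for Slc40a1, 0.0782 for Mpp1 and Cdkn2c, 0.13 for Tm7sf2). Slc40a1, the iron exporter ferroportin, rose by 0.76 (adjusted p = 0.0468) as the only member past the threshold of 26 heme and iron genes (median 0.04, camera adjusted p = 0.933). Mpp1 rose by 0.93 (adjusted p = 0.0242, with 0.06 on its weaker probe) among 26 red cell membrane genes, whose median was 0.02 but whose mean, −0.07, and test pointed down (camera adjusted p = 0.457). Cdkn2c, a cyclin-dependent kinase inhibitor, rose by 1.01 (adjusted p = 0.0235) among 17 imprinted and growth-arrest genes (median 0.03, camera adjusted p = 0.933). Tm7sf2, a sterol reductase, rose by 0.67 (adjusted p = 0.0485) among 25 cholesterol genes (median −0.00, mean 0.06 and test up, camera adjusted p = 0.994). In 5 lists 0 members passed: erythroid transcription factors (median −0.06, camera adjusted p = 0.287), heat shock proteins (−0.02, 0.151), oxidative phosphorylation (0.05, 0.933), autophagy (0.01, 0.976) and ribosomal proteins (0.01 with the test pointing down, 0.868). The median at the 75th percentile scaling was −0.16 for heme (camera adjusted p = 0.049), −0.19 for erythroid transcription factors (0.00576), −0.19 for heat shock (0.0244), −0.19 for oxidative phosphorylation (0.00397) and −0.20 for ribosomal proteins (0.00162), and each was past the threshold there, with adjusted p of 0.773 to 0.803 with an estimated correlation. Slide as a block ended each of these calls (camera adjusted p = 0.817 to 0.967), and the medians lay at percentiles 43.5, 28.9, 32.8, 52.3 and 42.3 of random lists matched on expression, in the same order.

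Among markers of other cell types, Cd68 rose by 0.73 (adjusted p = 0.0342, 0.131 with slide as a block) among 14 granulocyte and macrophage genes, whose median was 0.21 (camera adjusted p = 0.0808) and 0.82 at the 75th percentile scaling (camera adjusted p = 0.002; adjusted p = 0.532 with an estimated correlation), where slide as a block gave 0.30 and ended the call (camera adjusted p = 0.174). Of 17 lymphoid genes 0 passed (median 0.16, camera adjusted p = 0.457; 0.43 at the 75th percentile scaling with camera adjusted p = 0.0128, adjusted p = 0.764 with an estimated correlation, camera adjusted p = 0.805 with slide as a block and percentile 54.5 of matched lists), of 7 mast cell and basophil genes 0 (0.08, 0.894) and of 10 stromal and endothelial genes 0. The stromal list had a median of 0.39 (camera adjusted p = 0.128), 0.09 within slide 1, 1.11 within slide 3 and 0.60 with slide as a block (camera adjusted p = 0.024). SetD8 3 stood apart in this list: Sparc was 11.70 on it against 6.84 to 7.30 on the other arrays, Col1a2 9.14 against 6.78 to 7.38 and Col3a1 8.34 against 6.29 to 6.71 (log2 signal).

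There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. At the 75th percentile scaling the real split gave 0 genes and the highest of the others 0, so all 10 were as large, and after normexp and quantile normalization the real split gave 245 genes and the highest of the others 0, so that 1 of 10 was as large. The second setting was chosen for description after its count on the real split had been seen. Its 245 against 0 is therefore no separate support for the grouping.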
